A study of Mus musculus with 5 samples.

How the data were processed

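Total RNA from the hypothalamus of 3 anx/anx and 3 control mice was compared on 5 two-channel Agilent arrays. Per the labels' protocols, 500 ng of RNA was amplified and labelled by in vitro transcription, the RNA integrity numbers lay between 8.4 and 8.9, and the ratios of 28S to 18S RNA between 1.3 and 1.6. Affected animals were recognised by their body weight, tremor and behaviour. The arrays form 3 littermate pairs, with a technical dye exchange in pairs 1 and 2 and none in pair 3. Channel 1 carried Cy5 on 3 arrays and Cy3 on 2.

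The deposited values are log2 ratios, 1 per feature and array, for 44290 features with no missing value. Per the submitters' processing notes limma was used, with no version given. The base of the logarithm and the steps of background correction and normalization are not given in the sources used here, and base 2 was taken because limma works in it. Scale and centring are also not stated. The medians of the 5 arrays lay between -0.02 and 0.02 over all features. Single-channel intensities were not used here, so dim features could not be told from bright ones or left out.

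The direction of the ratios was worked out as follows. Across gene-named probes, the 2 arrays of each exchanged pair correlated above 0 (0.69 and 0.78), so the table already holds both arrays the same way round and no sign was changed. Another 728 features, none of them with a gene name, followed the dye instead: each exceeded 1 in size on all 5 arrays, with 1 sign on the 3 arrays with Cy5 in channel 1 and the other sign on the 2 arrays with Cy3 there. They were left out of all tests. Because of them, correlations over all features are negative within exchanged pairs (-0.72 and -0.42). That the ratios stand for anx/anx over control is likely from the labels, which name anx/anx first and whose first channel changes dye in the exchanged arrays, but no label states the numerator.

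Probes were named from the platform annotation, in which 32042 features have 1 gene symbol and 47 have several, while 12201 are unlisted and unnamed here. Of these probes, 31906 matched a RefSeq gene of the assembly GRCm38.p6 by Entrez identifier and 0 symbols needed an update. That table was used only for names, chromosomes, gene order and gene length. Probes of 1 gene were averaged, which gave 19087 named genes, 8266 of them with several probes. The remaining 11520 features, those with several symbols included, were tested singly, so that 30607 features were tested. Hmgb1-rs17, Gm5176 and ribosomal protein genes have close copies in the genome, which a probe may not separate.

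The comparison was fitted with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the 3 pair means, with the intercept tested against 0, two-sided, and p-values adjusted by Benjamini and Hochberg. A feature passed at an adjusted p under 0.05. Each pair counts as 1 replicate, which leaves 2 residual degrees of freedom. Errors are SDs over the 3 pairs. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over all lists of at least 5 measured genes, which were 37 of the 38 lists drawn up. The list of sex-limited genes fell short, and Ddx3y is not analysed here. The background of a list was all named genes, since only these could belong to a list. Estimated correlations and the rotation test fry were run beside it. For fits other than of pair means, camera was applied to the moderated statistics. Chromosome 2 was compared with the others by Fisher's exact test over the 18966 named genes with a chromosome.

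The groups, the tests, the lists and the rule for named genes were set before the data were examined. The rule takes up to 15 genes in each direction past the threshold. As fewer than 10 passed, it takes the 10 in each direction with the largest moderated statistic among genes at an unadjusted p under 0.01 with the same sign on all 5 arrays. From each list it takes members past the threshold, or otherwise 2 to 4 members with the largest mean and 1 sign in every pair. It also takes a fixed set of feeding peptides, Ndufaf1, Gfap, Mbp and Xist. Slc6a3, Tph2 and Dlx1 were named after their values were seen. The lists of brain regions other than cortex and thalamus were drawn up after the largest ratios of pair 1 had been seen, and their medians were set against 10000 random lists of named genes of the same size.

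The test was tried on simulated data with 30607 features, of which 200 were changed. At a log2 change of 0.5 it recovered 56.5% of the changed features, at 1 it recovered 99.5% and at 2 it recovered 100%. False calls numbered 8, 17 and 13 in turn. A list of 21 genes shifted by 0.2 was recovered by camera in 100% of 100 runs of independent genes, with 0.11 false lists per run. The simulated genes were independent, which real genes are not, so 0.11 does not measure how many false lists arise in these data. The noise of the simulated genes was normal, with the moderated variances of the fit. It had no part of its own for a pair or dye, so recovery in real data may be lower.

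Alternatives were fits of all 5 arrays with the pair as a random block or with a dye term, unswapped arrays only, arrays centred on the median or scaled to equal spread, each probe singly, robust shrinkage of variances, array weights, an adjusted p under 0.10, a ratio above 0.1 in size in at least 1 pair, and each pair left out in turn. For chromosome 2 the alternatives were the 100, 200 or 500 genes of smallest p. Added after the data were seen were a fit of named genes only, a background of all features, counts at an unadjusted p under 0.01, and list tests after a lowess trend with gene length (span 0.3) had been removed from each pair. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 in Python 3.11.15.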

Results

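Expression in the hypothalamus was compared between anx/anx mice and control littermates on postnatal day 16. The anx mutation is a spontaneous, recessively inherited mutation of the mouse, and homozygous animals eat poorly, stay small, shake and are mildly hyperactive. The labels give 3 animals of each kind, set against each other as 3 littermate pairs, and state that the controls were probably a mixture of wild-type and heterozygous animals, which cannot be told apart by eye. Each pair was hybridised to an Agilent array with one animal in the Cy5 channel and the other in the Cy3 channel. Pairs 1 and 2 were hybridised again with the dyes exchanged, which gave 5 arrays. The arrays of a pair were counted as 1 replicate, so that the fit of pair means had n = 3. This small number limits the precision of every value, and camera's p-values at a preset correlation do not show it. Neocortex, which the design text also names, is not analysed here.

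The design asks which genes of the hypothalamus differ in expression between an anx/anx mouse and its littermate. Among named genes with the same sign on all 5 arrays, the largest positive moderated statistics belonged to Hmgb1-rs17, a sequence related to Hmgb1, and Kcnd2, a voltage-gated potassium channel subunit gene. Their mean log2 ratios were 0.80 ± 0.12 and 0.55 ± 0.04 (SD, n = 3 pairs). The largest negative statistics belonged to Nmral1, with -0.54 ± 0.02, and Cd82, a tetraspanin gene on chromosome 2, with -0.53 ± 0.07. The 2 arrays of pair 1 had -0.86 and -0.18 for Cd82, -0.72 and -0.39 for Nmral1, 0.76 and 0.425 for Kcnd2, and 0.69 and 0.87 for Hmgb1-rs17. The SD over pair means leaves such differences out. Ranking by the moderated statistic also favours genes with a small SD over pairs. The probe of Hmgb1-rs17 may not separate it from its related copies. A positive ratio stands for more RNA in the anx/anx animal, a direction that is likely and not stated, since it rests on the order in which the labels name the 2 animals and on the dye of the first channel. Every direction given here would turn if the ratios ran the other way. None of the 30607 features tested passed the limma test after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.322.

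The 10 genes with the largest positive moderated statistic and the same sign on all 5 arrays also held Kcnq3, a further potassium channel subunit gene (0.50 ± 0.11), Map1b, a microtubule-associated protein of growing neurites (0.48 ± 0.07), Gabra2, a GABA-A receptor subunit (0.46 ± 0.06), and Celf4, an RNA-binding protein of neurons (0.45 ± 0.10). The remaining members were Gm5176, Rufy2, Spop and Tspan13, with means from 0.37 to 0.43. On the negative side, Ndrg1, a gene induced by low oxygen that is also needed by Schwann cells, had the lowest mean of the 10, -0.69 ± 0.14. Cebpd, a transcription factor gene that responds to glucocorticoids and cytokines, had -0.56 ± 0.10, and Kcnab3, an auxiliary subunit gene of potassium channels, had -0.52 ± 0.07. Entpd3, Rtkn, Cdc42ep1, Pigz and Plin3 lay between -0.51 and -0.40. Of 52 named genes with several probes, counted over all genes named by rule, 20 had probe means more than 0.3 apart and 6 had probes of both signs, so that the SD over pairs understates the error of such genes. The probes of Gabra2 ranged from 0.29 to 0.62 and those of Gm5176 from 0.27 to 0.69. Among the 125 genes named by rule, 22 had arrays of different sign within an exchanged pair. They include Usp18, Serping1, Mt2, Per1, Cyp51, Atp5b, Cox4i1, Rpl12, Psmb7, Lepr and Mbp, which are named with their lists. The 20 genes with the largest statistics could not be among them, since they were chosen for the same sign on all 5 arrays.

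**Figure D1:**
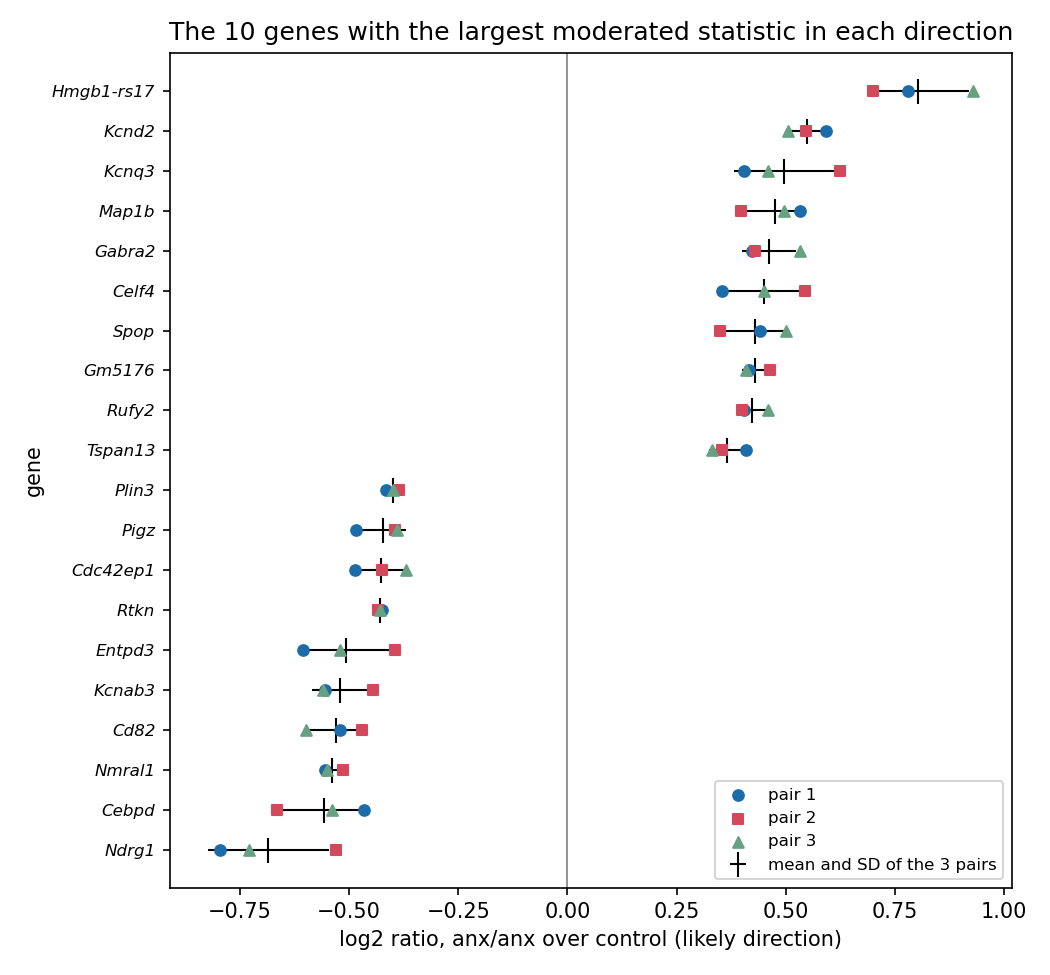
Log2 ratio of anx/anx over control (likely direction, x axis) of the 10 genes with the largest moderated statistic in each direction, with 1 point per littermate pair and the mean ± SD of the 3 pairs. Hmgb1-rs17 (0.80 ± 0.12) and Ndrg1 (-0.69 ± 0.14) lie farthest from 0, and no gene passed the adjusted threshold.

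At an unadjusted p under 0.01 there were 906 features where 306 would arise by chance, 549 of them higher and 357 lower in anx/anx. With the sign turned, 357 would be higher and 549 lower. This balance was absent without pair 2 (158 higher, 159 lower) and ran the other way on unswapped arrays only (580 higher, 763 lower). At an unadjusted p under 0.05 there were 3274 against 1530 by chance. Genes with a name and features without one differed in balance: of 528 named genes at an unadjusted p under 0.01, 241 were higher and 287 lower, while of 378 unnamed features 308 were higher and 70 lower (70 higher and 308 lower with the sign turned). The balance of named genes turned with each probe singly (648 higher, 420 lower), with a ratio above 0.1 in at least 1 pair (286 and 259) and without pair 1 (99 and 82). In the other fits more named genes were lower, after centring only as 267 to 266. The count of all features at this p was between 317 and 380 when any 1 of the pairs was left out, and it was 1502 and 1533 in fits of all 5 arrays with the pair as a random block or with a dye term. Testing only the 23505 features whose ratio exceeded 0.1 in size in at least 1 pair gave 86 features past the adjusted threshold, in a test whose filter was taken from the ratios themselves. Of these, 20 named genes and 53 unnamed features were higher, and 12 named genes and 1 unnamed feature were lower.

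Of 37 gene lists tested, 16 passed limma's camera test with a preset correlation of 0.01 between genes, 4 of them higher and 12 lower in anx/anx (12 higher and 4 lower with the sign turned). At the preset correlation, camera sets the genes of a list against the other named genes, and its p-values rest on the spread over genes. They do not measure how far a list varies between pairs, so a small p is no measure of agreement between animals. None of the 16 passed with a correlation estimated from these pairs (smallest adjusted p = 0.492). That test has only 2 residual degrees of freedom. In 5 of the 16 the estimated correlation was 0.01 or lower (-0.01 for complex I), so there a higher correlation between genes was not what ended the call. In the others it was above the preset value, from 0.02 for hypoxia and glycolysis to 0.61 for heat shock genes, with 0.26 for myelin. None passed the rotation test fry (smallest adjusted p = 0.250). After the trend with gene length had been removed all 16 passed, but 4 medians over gene means shrank by over 1.5 times, from -0.06 to -0.02 for the MHC, interferon and complement list, from -0.08 to -0.05 for unfolded protein genes, from -0.10 to -0.06 for complexes II to V and from -0.10 to -0.06 for the proteasome. No member of any list passed the threshold over all genes tested, while 12 of the 37 lists held at least 1 gene that passed when adjusted over the list alone. That adjustment does not account for the number of lists, and how many random lists would hold such a gene was not tested.

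The myelin list was the lowest. Its 25 measured genes encode myelin proteins, enzymes of myelin lipids and transcription factors of oligodendrocytes. They had a median of -0.24 ± 0.13 (mean and SD of the 3 pair medians) and all 25 had a mean below 0. The pair medians were -0.39, -0.15 and -0.175, so the list was lowest in pair 1. In 18 genes every pair was below 0, and 7 passed when adjusted over the list alone. Trf, the iron carrier transferrin, stood at -0.76 ± 0.50, Mal, a proteolipid of myelin membranes, at -0.51 ± 0.39, Cnp, an enzyme of non-compact myelin, at -0.48 ± 0.10, and Fa2h, which hydroxylates myelin lipids, at -0.39 ± 0.23. The list passed camera at an adjusted p of 6.6e-09, but had an adjusted p = 0.544 with an estimated correlation. The 3 probes of Mbp, the gene of myelin basic protein, disagreed, with means of 0.07, -0.19 and -0.45. The precursor markers of the oligodendrocyte lineage had a median of -0.01 ± 0.08 and did not pass (adjusted p = 0.876).

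Genes of cholesterol biosynthesis, whose product is a main lipid of myelin, were also lower as a list. The list had a median of -0.16 ± 0.16 over 19 genes (pair medians -0.335, -0.02 and -0.135, camera adjusted p = 0.00014). It had an adjusted p = 0.595 with an estimated correlation, and without pair 1 the list no longer passed (0.101). Mvk stood at -0.35 ± 0.07 and Mvd at -0.31 ± 0.06, both enzymes that carry mevalonate towards isoprenoids and the 2 genes that passed when adjusted over the list alone. Fdps had -0.28 ± 0.13, with probes at -0.45 and -0.11, and Cyp51 -0.27 ± 0.23.

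The list of mitochondrial complex I, the entry point of the respiratory chain, was lower by a small amount that was nearly the same in the 3 pairs. The median of 37 genes was -0.12 ± 0.01, their means ran from -0.39 to 0.06, 24 genes were below 0 in every pair, and the camera adjusted p was 5.81e-07. The list had an adjusted p = 0.492 with an estimated correlation. Ndufs8 had -0.39 ± 0.02, the only member to pass when adjusted over the list alone, while Ndufa6 had -0.26 ± 0.14 and Ndufa11 -0.25 ± 0.08. Ndufaf1, an assembly factor of complex I on chromosome 2, had -0.33 ± 0.22, with -0.33, -0.11 and -0.55 in the 3 pairs. Complexes II to V had a median of -0.08 ± 0.05 over 39 genes (camera adjusted p = 0.00054, and adjusted p = 0.544 with an estimated correlation). Examples were Atp5b at -0.24 ± 0.21, Cox4i1 at -0.21 ± 0.10 and Cyc1 at -0.19 ± 0.04. None of the 39 passed when adjusted over the list alone.

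Glycolytic and hypoxia-responsive genes had a median of -0.09 ± 0.05 over 24 genes (camera adjusted p = 0.00683, and adjusted p = 0.544 with an estimated correlation). Pfkfb3, a regulator of glycolytic flux, stood at -0.31 ± 0.09, with probes from -0.53 to -0.10, and Aldoc at -0.25 ± 0.12. The proteasome list had a median of -0.09 ± 0.04 over 28 genes (0.0063, and adjusted p = 0.717 with an estimated correlation), with Psmb7 at -0.29 ± 0.21 and Psmc5 at -0.24 ± 0.12 (probes at -0.40 and -0.08). Neither list held a gene that passed when adjusted over the list alone, and without pair 1 neither passed camera (0.121 and 0.207).

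Genes of GABA and glutamate transmission were higher as a list, with a median of 0.13 ± 0.04 over 27 genes (camera adjusted p = 1.09e-06, and adjusted p = 0.492 with an estimated correlation). Gad2, which makes GABA, had 0.52 ± 0.18, Gabra2 0.46 ± 0.06, the AMPA receptor subunit gene Gria2 0.33 ± 0.22 and the metabotropic glutamate receptor gene Grm5 0.30 ± 0.08. The probes of Gria2 ranged from 0.15 to 0.65, and those of Grm5 from 0.07 to 0.77. In 11 genes every pair was above 0, and 4 passed when adjusted over the list alone. General neuronal markers did not pass, with a median of 0.07 ± 0.19 (camera adjusted p = 0.63). Their pair medians were -0.03, 0.28 and -0.06, and without pair 2 camera's direction was lower (adjusted p = 0.624). Among them Syt1, a calcium sensor of synaptic vesicles, had 0.59 ± 0.29, with probes from 0.18 to 0.90. In 3 lists, none of which passed, the median over gene means was below 0 while camera's direction was higher (neurons, oligodendrocyte precursors, ependyma and tanycytes). The mean over genes and camera's direction differed for neurons, precursors and hypothalamic nuclei.

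The other lists that were higher drew more on pair 1. Cell cycle and neurogenesis genes had pair medians of 0.21, 0.03 and 0.03 (camera adjusted p = 1.79e-05, and adjusted p = 0.595 with an estimated correlation), with Mki67, a marker of dividing cells, at 0.27 ± 0.10 and Ccnd2 at 0.45 ± 0.60. Thalamic markers had pair medians of 0.57, 0.01 and 0.12 (0.00239, and adjusted p = 0.620 with an estimated correlation), led by Ntng1 at 0.65 ± 0.34 and Rora at 0.58 ± 0.34, the 2 genes that passed when adjusted over the list alone. The 13 probes of Ntng1 ranged from -0.06 to 0.81. Cytosolic ribosomal protein genes had pair medians of 0.10, -0.02 and 0.07 over 50 genes (0.000189, and adjusted p = 0.620 with an estimated correlation) and did not pass without pair 1 (0.0524). Rpl12 had 0.29 ± 0.23 and Rps2 0.21 ± 0.12.

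Lists of glucocorticoid-responsive, unfolded protein and heat shock genes were lower. Genes that respond to glucocorticoids had a median of -0.13 ± 0.08 over 21 genes (camera adjusted p = 0.000139, and adjusted p = 0.595 with an estimated correlation), and 12 of them were below 0 in every pair. Beside Cebpd, which passed when adjusted over the list alone, Tsc22d3 (a mediator of glucocorticoid action) had -0.41 ± 0.22, the metallothionein gene Mt2 -0.34 ± 0.30 and the clock gene Per1 -0.30 ± 0.29. Genes of the unfolded protein and amino acid starvation responses had a median of -0.10 ± 0.03 over 26 genes (0.00911, and adjusted p = 0.544 with an estimated correlation). The named members were those of the endoplasmic reticulum arm, Sdf2l1 (-0.38 ± 0.20), Pdia4 (-0.38 ± 0.13), Herpud1 (-0.36 ± 0.12) and Xbp1 (-0.30 ± 0.13), and 2 genes passed when adjusted over the list alone. Heat shock genes had pair medians of -0.34, 0.14 and -0.18 over 14 genes (0.0293, and adjusted p = 0.749 with an estimated correlation), with Cryab at -0.36 ± 0.10 and Bag3 at -0.33 ± 0.08 (probes at -0.60 and -0.07). Without pair 1 the unfolded protein list (0.121) and the heat shock list (0.463) did not pass, and the heat shock list did not pass without pair 3 (0.125) or on unswapped arrays only (0.126) either.

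Endothelial, blood cell and MHC lists were lower as well, while inflammatory genes and microglial markers did not pass. Endothelial and pericyte markers had a median of -0.12 ± 0.05 over 16 genes (camera adjusted p = 0.00239, and adjusted p = 0.544 with an estimated correlation), with Esam at -0.26 ± 0.08, Ly6c1 at -0.25 ± 0.07 and the tight junction gene Cldn5 at -0.22 ± 0.10. MHC, interferon and complement genes had a median of -0.08 ± 0.04 over 31 genes (0.0063, and adjusted p = 0.544 with an estimated correlation). Usp18 (-0.38 ± 0.14), Bst2 (-0.35 ± 0.14) and Ifit1 (-0.17 ± 0.07) are interferon-induced. Serping1, the gene of the C1 inhibitor, had -0.40 ± 0.23, but its arrays differed in sign in both exchanged pairs (-1.14 and 0.43 in pair 1), and those of Usp18 did in pair 1 (-0.78 and 0.02). The blood cell list rested on 8 genes with pair medians of -0.14, -0.32 and 0.08 (0.0434, and adjusted p = 0.620 with an estimated correlation). Without pair 1 the endothelial (0.0817) and blood (0.155) lists did not pass, and without pair 2 neither the blood (0.646) nor the MHC list (0.122) did. On unswapped arrays only, the blood list did not pass (0.0731).

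**Figure D2:**
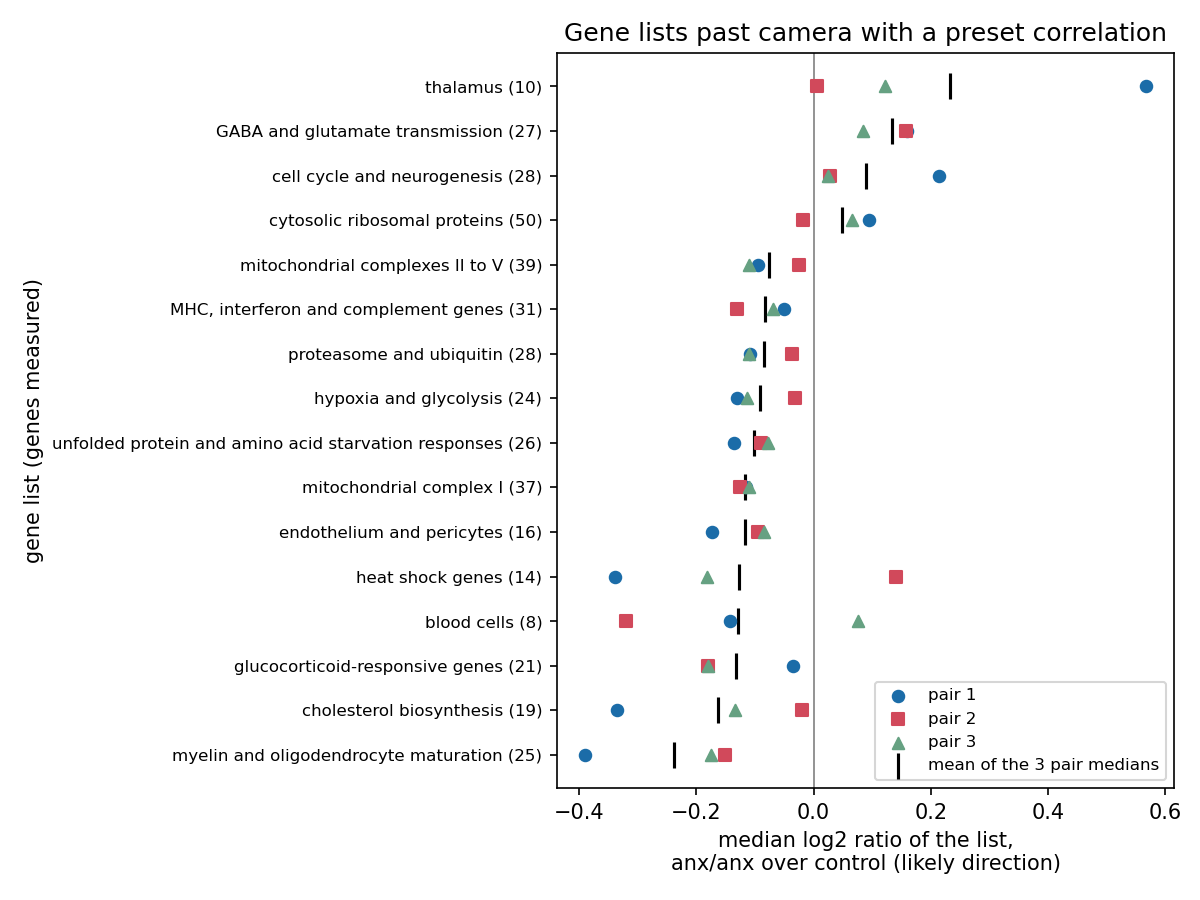
Median log2 ratio of anx/anx over control (likely direction, x axis) of the 16 gene lists that passed camera with a preset correlation, with 1 point per littermate pair, a bar at the mean of the 3 pair medians and the number of genes measured in brackets. The myelin list lies lowest at -0.24, and complex I has nearly the same median in the 3 pairs (-0.12 ± 0.01).

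Lists of feeding circuits did not pass. Orexigenic and anorexigenic neuropeptides had a median of -0.06 ± 0.02 over 21 genes (camera adjusted p = 0.376), receptors for feeding peptides and metabolic hormones 0.02 ± 0.02 (0.376), and leptin, insulin and IGF signalling 0.02 ± 0.05 (0.0807, and 0.0468 with each probe singly). Npy, an appetite-stimulating peptide gene of the arcuate nucleus, had 1.19, -0.65 and -0.28 in the 3 pairs, a spread far above its mean of 0.09. Cartpt, which encodes an appetite-suppressing peptide, had -1.59, 0.03 and 0.05, and Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, had -2.19, 0.28 and -0.43. Trh also differed between pairs, with 0.47, -0.26 and 0.07. Pomc had -0.13 ± 0.12 and was below 0 on all 5 arrays, and Hcrt had -0.03 ± 0.05. Grp and Ucn were the members of largest mean with 1 sign in every pair, at -0.46 ± 0.43 and -0.46 ± 0.44. Both were largest in size in pair 1, with -0.925, -0.39 and -0.07 for Grp and -0.965, -0.215 and -0.2 for Ucn. The leptin receptor gene Lepr had 0.17 ± 0.06, a value carried by 1 of its probes (0.36, against -0.02 for the other). Agrp and Crh are not analysed here.

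Among the other lists that did not pass, astrocyte markers had a median of -0.13 ± 0.16 (camera adjusted p = 0.376), microglia and macrophages 0.01 ± 0.09 (0.401, and higher without pair 2, 0.00992) and inflammatory genes -0.02 ± 0.04 (0.555). The pair medians of the astrocyte markers were -0.31, -0.08 and 0, and without pair 1 camera's direction was higher (0.878). Gfap, an intermediate filament gene of astrocytes, had -0.27 ± 0.23, while the astrocytic glutamate transporter gene Slc1a3 had 0.39 ± 0.26, with probes at 0.16 and 0.62. Apoptosis genes had -0.02 ± 0.02 (0.799), although Endog, a mitochondrial nuclease on chromosome 2, had -0.35 ± 0.01 and passed when adjusted over the list alone. The list of serotonin, dopamine and noradrenaline genes had -0.01 ± 0.04 (0.69), with the serotonin receptor gene Htr3a at 0.65 ± 0.22. Thyroid hormone targets had 0.01 ± 0.10 (0.919), with Thrsp at -0.33 ± 0.05. Immediate early genes had -0.04 ± 0.16 (0.732, and adjusted p = 0.938 with an estimated correlation of 0.32). Without pair 1 they passed as lower at the preset correlation (0.00038), and without pair 2 the direction was higher (0.382). Meningeal markers had -0.08 ± 0.39 (0.376), with Mgp at -0.64 ± 0.26, and fatty acid genes had -0.07 ± 0.05 (0.0583). The fatty acid list passed as lower under 10 of 16 alternatives, at adjusted p from 0.0209 to 0.0404 in the 9 that kept the threshold, but not without pair 1 (0.424) or with an estimated correlation (0.62). Xist, expressed from the inactive X chromosome of females, had 0.02 ± 0.05.

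Pair 1 stood apart from the other pairs in genes of particular brain regions. In this pair 137 named genes had a log2 ratio above 1 in size, against 25 in pair 2 and 42 in pair 3. The markers of cortex, hippocampus and striatum had a median of 0.59 in pair 1, -0.03 in pair 2 and -0.14 in pair 3. With lists drawn up after this was seen, markers of midbrain and raphe monoamine neurons had medians of -1.23, 0.11 and 0.07, those of the striatum and other subpallial forebrain 0.70, -0.05 and -0.03, and those of the lateral and posterior hypothalamus -0.45, -0.05 and 0.01. The dopamine transporter gene Slc6a3 was at -4.37 and -3.78 on the 2 arrays of pair 1, and Tph2, which makes serotonin in the raphe, at -3.50 and -2.64. Dlx1, a transcription factor gene of subpallial neurons, was at 2.91 and 2.63.

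**Figure D3:**
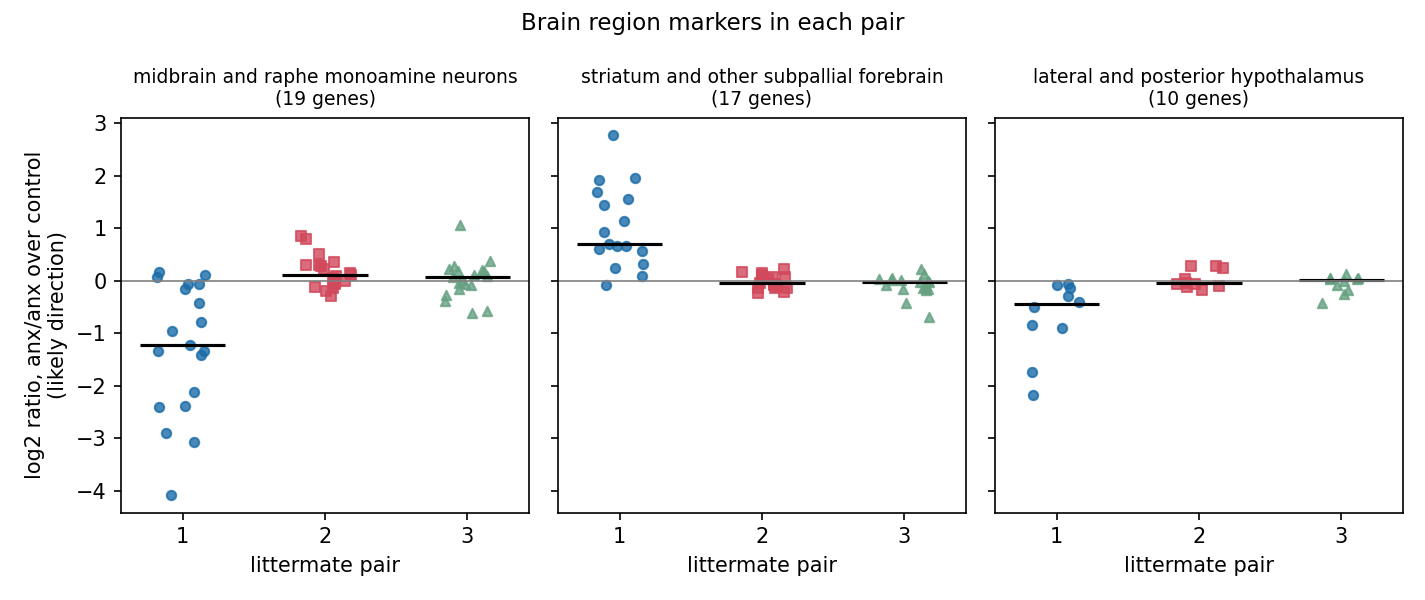
Log2 ratio of anx/anx over control (likely direction, y axis) of markers of 3 brain regions in the 3 littermate pairs (x axis), with 1 point per gene and a bar at the median. Pair 1 lies at -1.23, 0.70 and -0.45, while pairs 2 and 3 lie between -0.05 and 0.11.

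The anx mutation lies on chromosome 2, so that linked genes of another origin can differ between littermates. On this chromosome 36 of 1591 genes (2.26%) had an unadjusted p under 0.01, against 489 of 17375 (2.81%) on the others. The odds ratio was 0.80 with a 95% interval from 0.55 to 1.13, and Fisher's exact test, two-sided, gave p = 0.231, so no excess was detected. Without pair 2 the ratio was 1.41 (exact p = 0.168).

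The 2 arrays of a dye-swapped pair correlated at r = 0.69 in pair 1 and 0.78 in pair 2, across gene-named probes, which are not independent replicates. The means of different pairs correlated at 0.13, 0.23 and 0.26. Arrays of different pairs correlated more when the dyes were the same way round (0.13 to 0.32) than when they were exchanged (-0.02 to 0.17).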

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

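A group of features outside the comparison carried a strong signal, and the tests in this part were set against their explanations after the results were seen, although the fits with a dye term, with centred arrays and with a pair left out were planned. On all 5 arrays, 728 features without a gene name had ratios above 1 in size whose sign followed the dye and not the animal. Their medians were -5.18 and 4.33 on the 2 arrays of pair 1, -2.62 and 2.83 on those of pair 2, and -5.04 on the array of pair 3. None of the features with a gene name exceeded 1 in size on all 5 arrays in this way. At smaller sizes, the signs of the gene means of Serping1, Mbp and Xist did follow the dye on all 5 arrays.

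Region markers of pair 1 lay far from 0 in opposite directions, and an effect of the dyes is argued against by the exchanged array. There the midbrain and raphe list, drawn up after the largest ratios of pair 1 were seen, had a median of -1.04 (first array -1.39). The list of cortex, hippocampus and striatum had 0.54 (first array 0.63). It was fixed before the data were examined and is called the forebrain list from here on. For these 2 lists an effect of the genotype present in every pair is also argued against. The lower midbrain and raphe median of pairs 2 and 3 was 0.07, and the forebrain list had -0.03 and -0.14 there. In these lists pairs 2 and 3 also departed from random lists, in the other direction. The midbrain and raphe list was above the 95% range in both (0.11 and 0.07) and the forebrain list below it in pair 3. The thalamus list, also fixed before the data were examined, was above its range in pair 3 (0.12, upper bound 0.07), the direction it had in pair 1 (0.57). In pair 2 the thalamus list was within its range (0.01). Tissue boundaries that differed between the 2 animals of pair 1 may account for the pattern, with other differences between them left open: the forebrain list had a median of 0.585 in pair 1, where 95% of random lists lay between -0.09 and 0.08. The fixed list of serotonin, dopamine and noradrenaline genes, which also holds receptors, did not stand apart in pair 1 (-0.02, random lists -0.06 to 0.05), with genes from -4.08 to 1.95.

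The myelin, complex I and GABA and glutamate lists were weighed against 3 accounts. Without pair 1, which stood apart, the largest camera adjusted p of the 3 was 0.000204. The calls therefore did not rest on this pair alone. The medians of pairs 2 and 3 were -0.15 and -0.175 for myelin, -0.125 and -0.11 for complex I, and 0.16 and 0.08 for GABA and glutamate. As camera at the preset correlation does not measure variation between pairs, uneven dissection in pairs 2 and 3 is not excluded. Removing the trend with gene length, which in pair 2 had a Spearman correlation of 0.262 with the ratios, left at least 74.3% of each median, and all 3 lists passed. A smaller share of oligodendrocytes in the anx/anx tissue could lower the myelin list, in which all 25 genes had a mean below 0, but so could less RNA per cell, and bulk tissue keeps both open. With only 4 ways to turn the signs of the pairs, a share under 0.05 cannot be reached. The real signs gave 16 lists and the others 13, 12 and 4, so camera with a preset correlation called lists on turned signs too. Each turned pattern keeps 2 pairs the same way round, so a shift shared by them can remain, and the counts do not measure false calls.

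The surplus of small p-values came with an imbalance of unnamed features, 81.5% of which were higher (lower, with the sign turned) at an unadjusted p under 0.01. With a dye term the share on that side was 81.0%, which argues against an effect of the dyes as the whole cause, and on unswapped arrays only, where such an effect is not balanced out, it fell to 62.2%. Pair 3 correlated with the dye effect of pairs 1 and 2 about as well as with their mean ratio (0.29 and 0.30 across unnamed features, 0.34 and 0.28 across named genes), so a part in that pair is not excluded, although the median dye effect of the unnamed features at this p was 0.00. Centring tests nothing here (600 higher, 334 lower), as it moved the mean over pairs by only -0.0042. What these features share stays open, since their identity and brightness are not used here. Of the 4 sign patterns 1, the real one, reached 906 features, the highest of the others was 113, and 4 patterns are too few for a share under 0.05. For genes past the adjusted threshold the real signs and the highest of the others both gave 0, in 4 of 4 patterns.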

How the results depend on the processing

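No feature passed the adjusted threshold in limma under any alternative except the minimum ratio of 0.1 in size in at least 1 pair, which gave 86 features, 10 of them genes named here. That filter tests fewer features (23505) and uses the ratios themselves. Against 906 features at an unadjusted p under 0.01, there were 1502 with the pair as a random block, 1533 with a dye term, 1389 with each probe singly, 542 among named genes only and between 317 and 380 with 1 pair left out. More features were tested with each probe singly (43562 against 30607), and fewer genes or pairs in the last 2. For the fits of all 5 arrays the cause was not tested. Unswapped arrays turned the balance to 580 higher and 763 lower, and without pair 2 it was 158 to 159. The 16 lists became 0 with an estimated correlation and 0 with fry. With 1 pair left out there were between 9 (without pair 1) and 18 lists, and 7 of the 16 passed in all 3 such fits. Unswapped arrays lost heat shock (0.126) and blood (0.0731) and kept the other 14, and the other alternatives kept all 16. Of the lists that did not pass, fatty acid genes passed under 10 of 16 alternatives, the forebrain list under 6, leptin, insulin and IGF signalling under 2, and choroid plexus, microglia, meninges and immediate early genes each in 1 fit without a pair. The counts of 10, 6 and 2 include the looser adjusted p under 0.10. The odds ratio of chromosome 2 was between 0.741 and 1.41 with 1 pair left out, above 1 only without pair 2 (exact p = 0.168). Spearman's rho was 0.507 and 0.654 within the exchanged pairs and 0.423 for the first arrays of pairs 1 and 3, for which Pearson's r was 0.323. Of 125 named genes, 116 had 1 sign under every alternative and on every probe. Genes outside the fixed set had been chosen for 1 sign in every pair. The fits without a pair could therefore not turn their signs and say nothing on their stability. Only 52 of the 125 had several probes, and robust shrinkage and the minimum ratio do not change a gene's mean. Part of the count of 116 was thus fixed in advance. Cartpt, Npy and Trh changed sign without pair 1, Xist with unswapped arrays and between probes, and Fosl2, Lepr, Mbp, Ntng1 and Pkm between probes. Named genes only, the added backgrounds and gene length were chosen after seeing the data. Scaling moved nothing, as the arrays already had equal median absolute values, and with no missing value the alternative for missing values gave none. No signal over background was used here, so its limit is unknown.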

Other observations

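Some genes outside the passing lists, named after their values were seen or by the rule for named genes, had 1 sign in every pair, by unequal amounts. Htr2a, a serotonin receptor gene, had 0.33 ± 0.03 and passed, with Htr3a, when adjusted over the list alone of serotonin, dopamine and noradrenaline genes. Ppargc1a, a coactivator that drives mitochondrial gene expression, had 0.34 ± 0.12 (probes at 0.12 and 0.56), opposite in sign to the complex I list, and Scd1, a fatty acid desaturase gene, had -0.38 ± 0.20. None of these passed over all genes tested. Socs2 had 0.78, 0.30 and 0.05 in the 3 pairs, and its probes had 0.08 and 0.67.

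In pair 1 the choroid plexus transcript Ttr had a ratio of 1.91, against 0.02 in pair 2 and 0.03 in pair 3. Meningeal markers had medians of -0.38, -0.23 and 0.36 in the 3 pairs, and without pair 3 that list passed camera as lower at the preset correlation (adjusted p = 1.5e-08). Over all pairs its estimated correlation was 0.61, with which the adjusted p was 0.864. The remaining lists that did not pass were the forebrain (0.14 ± 0.39, camera adjusted p = 0.0806, but called under 6 of 16 alternatives, 1 of them the looser adjusted p under 0.10), choroid plexus (0.06 ± 0.10, 0.143, and 0.0209 without pair 2), circadian clock (0.00 ± 0.05, 0.602), other hypothalamic peptides (-0.02 ± 0.11, 0.869), pituitary (0.01 ± 0.07, 0.876), ependyma and tanycyte (0.00 ± 0.06, 0.876) and hypothalamic nuclei (-0.02 ± 0.05, 0.915) lists. Without pair 1 camera's direction for the forebrain list turned to lower (adjusted p = 0.121).

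A hypothesis chosen after the data were seen was that a linked segment of another origin around Ndufaf1 holds an excess of changed genes. Of the 201 genes that reach 100 genes to either side of it, 2 (0.995%) had an unadjusted p under 0.01, against 2.79% elsewhere. The odds ratio was 0.351, with an interval from 0.04 to 1.29 (Fisher's exact test, two-sided, p = 0.188). No excess was found, and with 2 genes a modest one is not excluded.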
